A study of Mus musculus with 4 samples.

How the data were processed

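The data are Visium measurements of 4 frozen sections of mouse uterus with day 6 implantation sites, 2 from control mice with floxed Wwtr1 alleles and 2 from TAZ uKO mice that also carried Pgr-Cre. Groups and replicate numbers were read from the sample labels. Per the labels' protocols, sections on the arrays were treated with proteinase K (30 min in the sample labels, 40 min in the series design) and hybridized with the spatial tags, and the series design names DNBseq sequencing. The deposited matrices hold raw UMI counts per gene and spot, which the authors made by aligning reads to mm10 (GRCm38) and counting UMIs. The submitters' processing notes name Cell Ranger for this step, while the file headers name spaceranger 2.0.1. As deposited, the matrices keep only spots under tissue, 3808 in all, and each section's matrix was given in 2 identical copies, of which 1 was read. Image scale factors were not used. Gene coordinates are from the RefSeq annotation of GRCm38.p6.

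Counts were checked to be whole numbers, and spot barcodes were matched to array positions. The sections had 28483067 and 12554771 UMIs (control 1 and 2) and 19852732 and 18261348 UMIs (TAZ uKO 1 and 2), with medians of 5078, 6139, 5279.5 and 5479.5 genes per spot. Mitochondrial transcripts made up 0.699%, 0.827%, 0.859% and 0.826% of UMIs and hemoglobin transcripts 0.0172%, 0.0205%, 0.046% and 0.0503%. All spots were kept. A stricter set (at least 1000 UMIs and at most 25% mitochondrial) held 1524, 464, 941 and 847 spots and was used as an alternative. Tissue pieces were groups of at least 100 joined spots. Genes whose symbol is shared by several identifiers (38 symbols) were kept apart by identifier.

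For clustering with scanpy 1.11.5 (Python 3.11.15), genes seen in at least 10 spots were used. Counts were scaled to 10000 per spot and log-transformed, 2000 variable genes were chosen and scaled within each section, and 30 principal components with 15 neighbours were clustered by the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at resolution 0.6. A cluster took the name of a structural list (decidualization, smooth muscle, epithelium, uterine gland, NK cell or lymphatic endothelium) when its score was at least 0.4, a limit set after the scores were seen. Scores are mean log2 ratios of list members in a cluster over the other spots of the section, with 5 CPM added. Cluster 7 scored highest for epithelium (2.397) but has other leading genes, so it kept its number. Its decidualization score (1.047) was above those of clusters 3 and 9 (0.7676 and 0.4375), which made the decidual region. Its trophoblast score (1.338) was higher still. Clusters under the limit for all 6 lists made the outer stroma region. A cluster whose median UMI count was under 0.33 of its section's median was not named. Leiden resolutions 0.3 and 1.0 and scaling over all sections together were alternatives. Region shares were given exact binomial 95% intervals and an exact permutation test.

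Counts were summed per section, and per section and region with at least 20 spots. Region sums held 2118318 to 3997942 UMIs (decidual), 1578237 to 4427551 (muscle), 5182982 to 11615086 (outer stroma), 1441260 to 2637713 (granzyme-led), 752654 to 1202988 (cluster 7) and 697307 to 2889832 (vascular). Sums were tested with the edgeR 4.0.16 quasi-likelihood test (R 4.3.3) after filterByExpr and TMM normalization, with genotype as the only term and the section as the unit. Values printed as log2 differences are TAZ uKO minus control with the model's standard error, and p-values were adjusted by the Benjamini-Hochberg method with calls at 0.05. The interaction fit tested region by genotype on 8 sums of the decidual and muscle regions, with section as a block. Alternatives were DESeq2 1.42.0, limma voom (limma 3.58.1), RLE normalization, no low-count filter, a minimum of 10 CPM, a replicate block, leaving out each section, leaving out mitochondrial, hemoglobin and ribosomal protein genes, 250 random spots per section and other sets of spots. The whole-section biological coefficient of variation was 0.184.

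Gene lists (35 lists, 532 members, 525 in the files) were tested with camera of limma at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. Named genes are Wwtr1, Yap1 and Pgr. Beside them stand the genes of largest change among those that passed with at least 10 CPM and both TAZ uKO sections on the same side of both control sections, filled by smallest p where few passed, and up to 4 members of each list. Predicted genes and mitochondrial genes were not named. Genes of near-identical sequence (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Hspa1a and Hspa1b, granzymes, prolactins, C4b) may share reads, so their separate levels are uncertain. Of 295 named symbols, 289 were in the annotation table.

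The tests were tried on 1 random draw of simulated data with 100 genes changed 2-fold and 100 others changed 4-fold. At a 2-fold and a 4-fold change the whole-section fit recovered 32 and 78 of them, the decidual fit 18 and 81, the muscle fit 31 and 90, the outer stroma fit 45 and 96 and the interaction fit 7 and 75. Among unchanged genes these fits called 11, 5, 14, 20 and 8. The number recovered at a 2-fold change shows how much a fit of 2 against 2 sections misses in this setting. Simulated genes varied independently and with the same spread in both groups. In the data the TAZ uKO pair varied more (SD of log2 level 0.328 against 0.153), and list genes can move together. A list shifted by 0.5 on the log2 scale was found with the preset correlation, which also called 2 unchanged lists, and was missed with an estimated correlation. Figures were drawn with matplotlib 3.10.9. The epithelial fit was left out for lack of gland spots, and nothing was taken from images.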

Results

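Gene expression was measured in sections of mouse uterus taken through implantation sites on day 6 of pregnancy, counting the day of the vaginal plug as day 1. An implantation site holds the embryo and the decidua, the tissue that the stromal cells of the uterus form around it. The method was Visium, in which a tissue section lies on an array of barcoded spots that capture polyadenylated RNA at known positions. Each captured RNA molecule carries a unique molecular identifier (UMI), so that it is counted once however often it is sequenced. The 4 sections fell into 2 groups of 2, which the labels call biological replicates. Control sections came from mice with floxed alleles of Wwtr1, the gene of TAZ, a transcriptional co-activator that the Hippo pathway restrains. TAZ uKO sections came from mice that also carried Pgr-Cre, a Cre recombinase expressed from the progesterone receptor locus and active in the uterine cells that express this receptor. Control sections 1 and 2 had 1530 and 478 spots under tissue with 28483067 and 12554771 UMIs. TAZ uKO sections 1 and 2 had 946 and 854 spots with 19852732 and 18261348 UMIs. The median spot held 17585 and 26804.5 UMIs in the control sections and 19415 and 20936 in the TAZ uKO sections. Control section 1 held 3 separate tissue pieces of at least 100 joined spots, control section 2 held 1, and each TAZ uKO section held 2. The labels do not say how many animals gave these pieces, so the section, not the piece or the spot, was the replicate in every test (n = 2 per group). An exact two-sided permutation test of 2 sections against 2 cannot give a p below 0.333, so gene calls rest on models that share information across genes. The control pair was more alike than the TAZ uKO pair, with a standard deviation (SD) of log2 level between replicates of 0.153 against 0.328 over 9353 genes.

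Spots of all sections were clustered together by their expression, and clusters were named by their score for fixed lists of structural genes. The decidual region was led by Krtdap, Hamp, Lrat, Crabp1 and Igfbp3. The outer stroma region held 3 clusters led by Tacstd2 and Coch, by Sfrp4 and Itga8, and by Gli1 and Wnt5a. The largest of them was the Sfrp4 cluster in control section 1 and the Tacstd2 cluster in the other sections. A muscle region held a cluster led by the smooth muscle genes Myh11 and Tagln and a smaller one led by Nppa, Tnni2 and Angptl7. A vascular region was led by the lymphatic genes Ccl21a and Mmrn1 with Eln (elastin), and a gland region by the secreted proteases Prss28 and Prss29 with the protease inhibitor Spink1. The vascular region takes its name from the lymphatic list only (score 1.729). Its scores were 1.307 for smooth muscle, 1.178 for uterine fibroblasts and 0.2465 for endothelium. A granzyme-led region carried Gzmd, Gzmf, Gzmb and Prf1, the cytotoxic granule genes of natural killer (NK) cells. Cluster 7, led by the prolactin family genes Prl3c1, Prl6a1 and Prl8a2 with Serpine1 and Hopx, was kept under its number. Its spots, left out of the decidual region, scored higher for decidualization genes (1.047) than the clusters of that region (0.7676 and 0.4375). That list holds Prl3c1 and Prl8a2, which lead this cluster. The same spots scored 2.397 for epithelium, 1.338 for trophoblast and 0.7822 for epiblast and visceral endoderm, so they need not be decidua alone. The last cluster, of 13 to 17 spots per section with few UMIs, was not named.

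**Figure D1:**
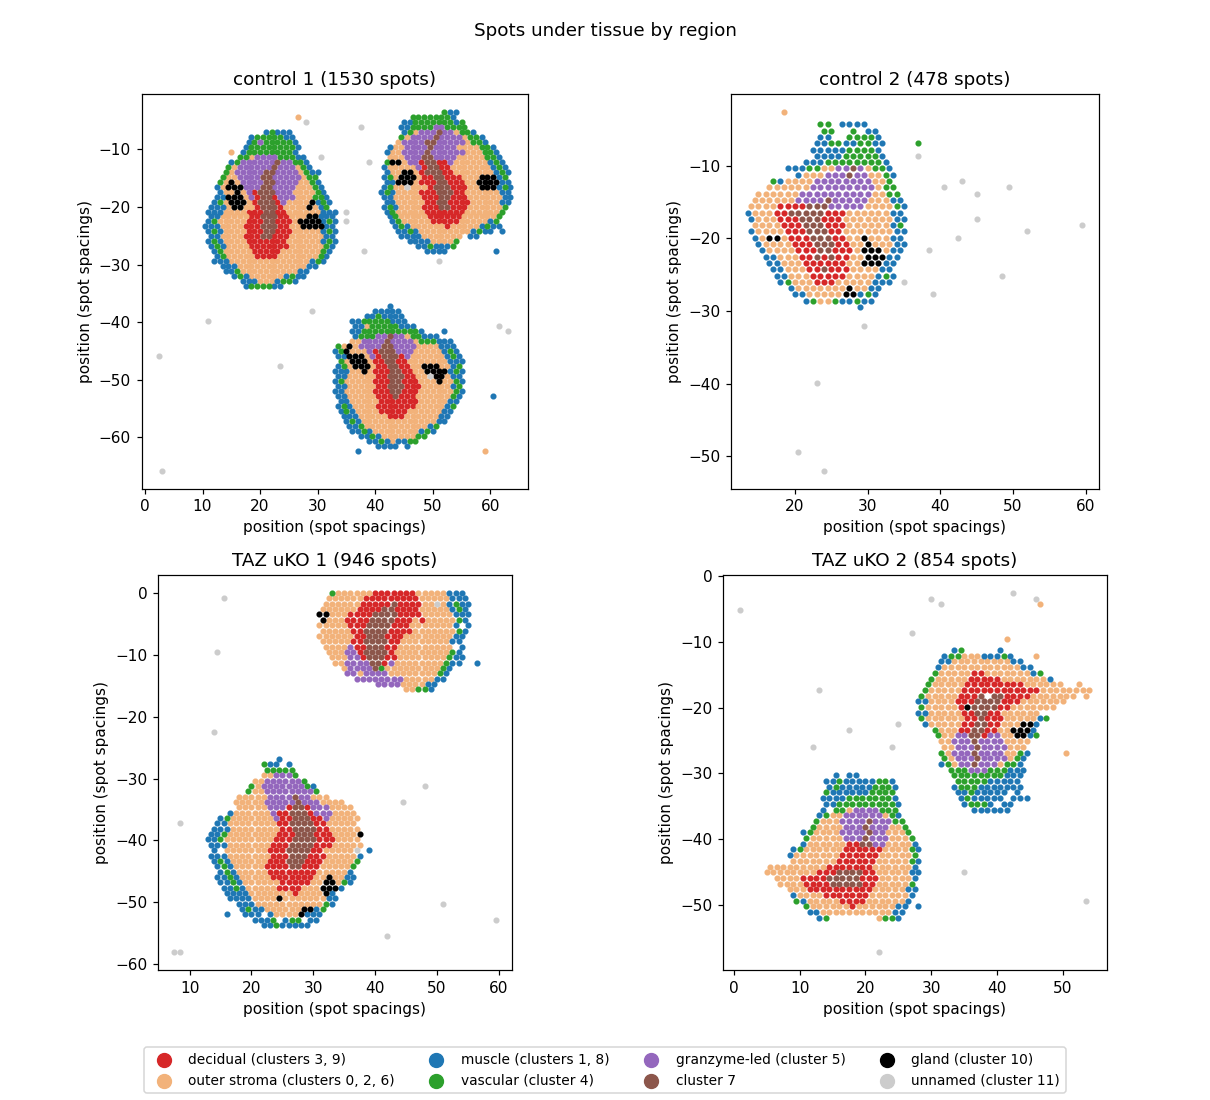
Spots under tissue at their array positions in the 4 sections, coloured by region, with axes in spot spacings. The gland region held 67 and 16 spots in control sections 1 and 2 and 15 and 8 spots in TAZ uKO sections 1 and 2.

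Region shares of the spots were compared between the 2 groups, though no exact test of 2 against 2 sections can call a difference. Outer stroma made up 33.7% ± 1.27 of control spots (mean ± SD, n = 2) and 42.5% ± 3.68 of TAZ uKO spots, and the decidual region 13.2% ± 0.844 and 16.2% ± 1.58. Muscle made up 19.3% ± 0.024 and 14.4% ± 2.22, the granzyme-led region 9.8% ± 0.64 and 8.84% ± 0.246, and the gland region 3.86% ± 0.73 and 1.26% ± 0.459. The 2 groups did not overlap in these 5 of 7 regions (exact permutation p = 0.333 each, the smallest possible). They overlapped for the vascular region (exact p = 0.667) and cluster 7 (exact p = 1). Chance alone leaves 33.3% of values without overlap, and the shares of a section are not independent of each other. The clusters of outer stroma did not move alike. The Tacstd2 cluster held 13.9% and 13% of spots in control sections 1 and 2. In TAZ uKO sections 1 and 2 it held 20.5% and 19.7%. The Gli1 cluster held 6.21% and 9.41% against 11.2% and 11.9%. The Sfrp4 cluster held 14.5% and 10.5% against 13.4% and 8.31%, with overlap. For the gland region the exact binomial 95% intervals (Clopper-Pearson, counting error only) were 3.41% to 5.53% and 1.93% to 5.38% in control sections 1 and 2, and 0.89% to 2.6% and 0.405% to 1.84% in TAZ uKO sections 1 and 2. Of the 119 leading genes of the clusters, 78 had an unadjusted p under 0.05 in at least 1 fit, whether or not they passed correction. The spots were clustered again without these 78, a step chosen after the shares were seen. Then 3 regions were without overlap: outer stroma (39.6% ± 0.571 against 45.4% ± 2.22), vascular (6.48% ± 0.0105 against 3.97% ± 0.837) and gland (1.75% ± 0.397 against 0.816% ± 0.491), and 87.3% of spots stayed in the same region. With scaling over all sections together the granzyme-led region turned direction (7.59% ± 0.0818 against 14.3% ± 7.29, without overlap), and so did the decidual region (12.7% ± 2.2 against 11.7% ± 1.16, with overlap). That scaling gave clusters made of 1 section. In the granzyme-led region 162 spots, also led by Aldh1a3, Ndp and Wnt5a, formed a cluster found only in TAZ uKO section 1. The share was 19.45% in that section and 9.13% in TAZ uKO section 2, so the turn rests largely on 1 section. The granzyme-led region was also higher in TAZ uKO sections on average with coarser clustering (17.1% ± 2.98 against 19.8% ± 2.14, with overlap). Its cluster of 677 spots there was also led by Wnt5a and Gli1, genes of an outer stroma cluster. The gland share overlapped there too (16.6% ± 3.72 against 13.1% ± 4.79, exact p = 0.667). That cluster of 601 spots was also led by Sfrp4, Igkc and Igha, genes of another outer stroma cluster. Neither coarser share measures its region alone.

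Wwtr1 transcript was not lower in the TAZ uKO sections. This gene, on chromosome 3 from 57455644 to 57575910 of GRCm38, had 68.1 and 65.3 CPM (counts scaled to the same TMM-normalized total in each section) in control sections 1 and 2 and 87.9 and 71.3 CPM in TAZ uKO sections 1 and 2. The log2 difference of TAZ uKO from control was 0.25 ± 0.14 (SE; adjusted p = 0.997), and it was 0.32 ± 0.23 in the decidual region, 0.18 ± 0.16 in muscle and 0.26 ± 0.16 in outer stroma. Over the whole sections it ranged from 0.09 without TAZ uKO section 1 to 0.39 without TAZ uKO section 2. Spots capture RNA at its poly(A) end, which may lie outside the deleted part of the gene, so this level does not show whether the gene was deleted. Yap1, the paralog of Wwtr1, on chromosome 9 from 7931999 to 8004638, was at 63.9 ± 0.857 CPM in control and 69.1 ± 0.0991 CPM in TAZ uKO sections (log2 difference 0.11 ± 0.11, adjusted p = 0.997). Pgr, the progesterone receptor gene, on chromosome 9 from 8898900 to 8968611, was at 69.2 ± 5.68 and 61.2 ± 9.25 CPM, with overlap between the groups (log2 difference -0.18 ± 0.15, adjusted p = 0.997).

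The first comparison asked which genes differ in the implantation site as a whole between mice with and without Pgr-Cre, all with floxed Wwtr1 alleles. In this design an effect of Pgr-Cre itself cannot be told from one of Wwtr1 loss. The gene with the smallest p was Spon2, which encodes a secreted matrix protein of the spondin family and lies on chromosome 5 from 33213518 to 33218254. It was at 130.6 ± 0.457 CPM in control and 464.6 ± 34.3 CPM in TAZ uKO sections, a log2 difference of 1.83 ± 0.13 (adjusted p = 0.29). Crabp1, a carrier of retinoic acid in the cytosol (50.1 ± 6.28 against 136.8 ± 24.3 CPM), Igfbp3, a binder of insulin-like growth factors (693.8 ± 20.2 against 1351 ± 74 CPM), and the hemoglobin genes Hbb-bs, Hbb-bt and Hba-a2 were also higher in both TAZ uKO sections. Hbb-bs was at 104.2 ± 14.5 CPM in control and 272 ± 8.86 CPM in TAZ uKO sections. The lower genes with the smallest p were Guca2b, a peptide secreted by epithelia (-2.43 ± 0.25), Angptl7, a secreted angiopoietin-related protein (-1.99 ± 0.22), the fibrillar collagen Col11a1 (-1.67 ± 0.21), the collagen-binding proteoglycan Fmod (-1.57 ± 0.19), the pentraxin Nptx2 (-1.47 ± 0.16) and the hyaluronan-associated protein Itih5 (89.1 against 44.7 CPM). None of these genes passed correction (adjusted p = 0.521 for each except Spon2), and edgeR called 0 of 14608 genes, with 728 (4.98%) at an unadjusted p under 0.05. Guca2b, Angptl7 and Itih5 are among the leading genes of clusters with lower shares of spots in both TAZ uKO sections. Crabp1 and Igfbp3 lead a cluster with higher shares there. For these genes a change in level cannot be told from a change in shares. DESeq2 called 89 (29 higher and 60 lower) and limma voom 0. The edgeR test called 349 without TAZ uKO section 1 and 522 without TAZ uKO section 2, where the spread rests on the control pair. The sections of the groups did not overlap for 33.3% of genes, and chance alone gives 33.3%.

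**Figure D2:**
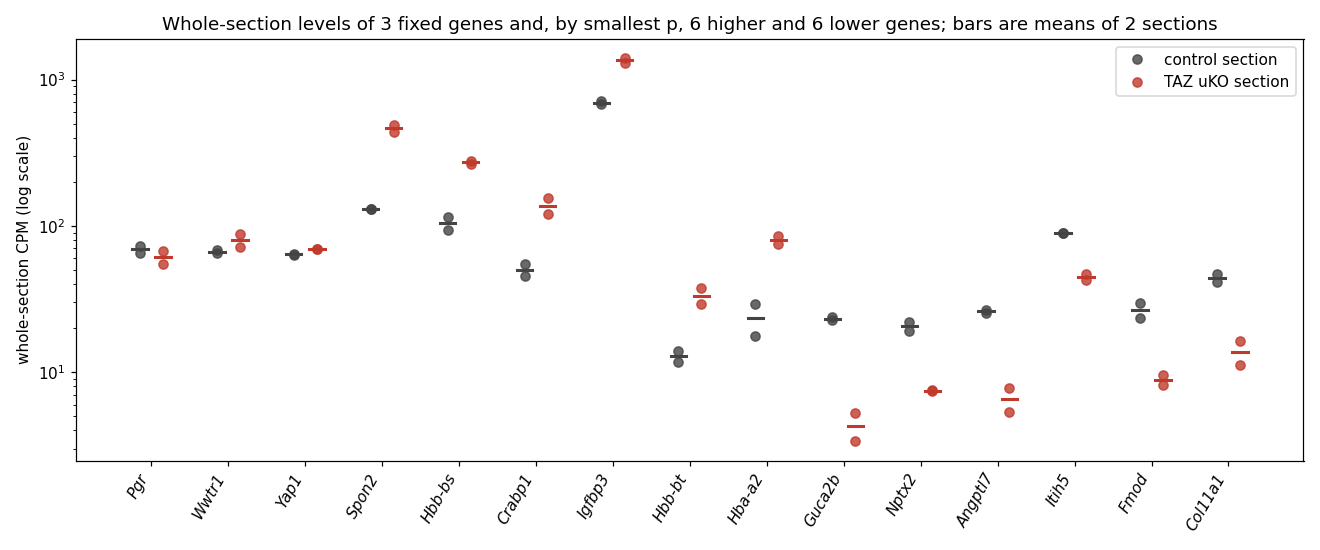
Level of Wwtr1, Yap1, Pgr and, by smallest p, 6 higher and 6 lower genes in each whole section, in CPM on a log axis, with points for sections and bars for group means. Spon2 was at 130.6 CPM in control and 464.6 CPM in TAZ uKO sections on average.

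Gene lists fixed before the data were examined showed more than single genes did, but only with a preset correlation between genes in the list test. The camera test, which compares a list with all other genes, called 16 of 35 lists with a preset correlation of 0.01 between genes, 5 higher and 11 lower in TAZ uKO sections. None was called with an estimated correlation, where the lowest adjusted p was 0.5. For some lists the estimate was itself under 0.01, such as 0.00373 for YAP and TAZ targets. No list member passed over all genes in the whole-section, decidual or outer stroma fits.

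Known targets of YAP and TAZ were lower as a list in the whole sections, with 19 of 22 members lower (median log2 difference -0.22, adjusted p = 0.000796, and adjusted p = 0.5 with an estimated correlation). Adjusted over the list alone, 1 member was higher, Igfbp3, and 2 were lower, among them Ccn2, a matricellular growth factor (-1.18 ± 0.22). Amotl2, a Hippo pathway scaffold, differed by -0.70 ± 0.15 and Ccn1, a relative of Ccn2, by -1.72 ± 0.51 (107.3 ± 42.5 against 32.6 ± 20.7 CPM). This call was lost without TAZ uKO section 2 (adjusted p = 0.0619). Core genes of the Hippo pathway were not called (adjusted p = 0.653). Immediate early genes, which respond within minutes to stimuli including tissue handling, were lower, with 11 of 13 lower (median -0.82, adjusted p = 3.58e-14, and 0.501 as an adjusted p with an estimated correlation) and 8 lower adjusted over the list alone. Among them Egr1 differed by -1.86 ± 0.37, Nr4a1 by -1.18 ± 0.32 and Dusp1 by -0.86 ± 0.21. Heat shock genes were higher (8 of 10, median 0.47, adjusted p = 0.00427, and 0.616 as an adjusted p with an estimated correlation). Over the list alone Hspa1a (1.16 ± 0.27) was higher and Hspb1 (-0.67 ± 0.12) lower. The list turned direction without TAZ uKO section 2 (adjusted p = 0.371).

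Markers of cell types differed in the same sections. Smooth muscle genes were lower (12 of 13, median -0.61, adjusted p = 1.29e-18, and 0.5 as an adjusted p with an estimated correlation), 8 of them adjusted over the list alone. Among them was Actg2, an actin of smooth muscle, at 1718 ± 116 against 844.4 ± 83.2 CPM. Uterine gland genes were lower (4 of 5, median -1.69, adjusted p = 2.42e-06, and 0.5 as an adjusted p with an estimated correlation). Prss28 was at 1158 ± 323 against 246.6 ± 210 CPM and Spink1 at 2087 ± 659 against 361.9 ± 371 CPM, and none passed over the list alone. Erythroid genes were higher (5 of 5, all 5 adjusted over the list alone, median 1.38, adjusted p = 5.73e-28, and 0.5 as an adjusted p with an estimated correlation). NK cell genes were lower (11 of 11, median -0.66, adjusted p = 3.73e-07) and macrophage genes higher (12 of 15, median 0.32, adjusted p = 0.000498), each with an adjusted p of 0.524 with an estimated correlation and none over the list alone. Among these, the granzyme Gzmc was at 49.1 ± 6.02 against 25.7 ± 7.68 CPM and the complement gene C1qb at 55.4 ± 5.77 against 82 ± 7 CPM. The NK cell call was lost without TAZ uKO section 1 (adjusted p = 0.106) and the macrophage call without control section 2 (0.0752) or TAZ uKO section 2 (0.137). Neutrophil genes were higher (3 of 3, 1 over the list alone, adjusted p = 0.00276, lost without TAZ uKO section 1 at 0.113). T and B lymphocyte genes were lower (6 of 7, adjusted p = 0.0388, lost without control section 1 at 0.281, TAZ uKO section 1 at 0.574 or TAZ uKO section 2 at 0.0535). Pericyte genes were lower (6 of 9, adjusted p = 0.0286), a call lost without control section 1 (0.0997), control section 2 (0.104) or TAZ uKO section 2 (0.19). These 3 lists had an adjusted p of 0.524 with an estimated correlation. Epithelium genes were not called (9 of 15 lower, adjusted p = 0.0738), nor were lymphatic endothelium genes (4 of 5 higher, adjusted p = 0.37), with none of either over the list alone.

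Progesterone response genes were lower as a list (15 of 19, median -0.19, adjusted p = 0.00973, and 0.501 as an adjusted p with an estimated correlation). Only the TAZ uKO mice carried Cre at the progesterone receptor locus, so this shift cannot be tied to Wwtr1 loss alone. Fkbp5, a co-chaperone of steroid receptors, was at 60.2 ± 0.316 CPM in control and 35.3 ± 3.42 CPM in TAZ uKO sections and was the only member lower over the list alone. The call was lost without TAZ uKO section 1 (adjusted p = 0.0723). Decidualization genes were not called in either direction (14 of 25 higher, median 0.01, adjusted p = 0.43). Adjusted over the list alone, Inhbb, a subunit of activin B (21.1 ± 2.85 against 68.5 ± 28.1 CPM), and Alpl, an alkaline phosphatase that marks decidual cells (103.9 ± 0.57 against 205.6 ± 46 CPM), were higher, and Ptgs2, the inducible prostaglandin synthase (21.4 ± 0.939 against 11.8 ± 0.606 CPM), was lower. The estrogen response list was not called either (adjusted p = 0.126, 2 members higher and 2 lower over the list alone).

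Collagen and matrix genes were lower (21 of 30, median -0.11, adjusted p = 0.00295, and 0.524 as an adjusted p with an estimated correlation). Col6a3, a chain of type VI collagen, was at 700.5 ± 33.5 against 382.9 ± 121 CPM. The call was lost without control section 1 (adjusted p = 0.114). Interferon response genes were lower (18 of 21, median -0.29, adjusted p = 0.00546, and 0.616 as an adjusted p with an estimated correlation), lost without control section 1 (0.455) or TAZ uKO section 2 (0.0554). Cholesterol synthesis genes were lower (14 of 15, adjusted p = 0.0343, and 0.781 as an adjusted p with an estimated correlation), lost without TAZ uKO section 1 (0.132) or TAZ uKO section 2 (0.137) and turned without control section 1 (0.409). Genes of the mitochondrial genome were higher (11 of 12, adjusted p = 0.0209, and 0.76 as an adjusted p with an estimated correlation), lost without control section 1 (0.805), TAZ uKO section 1 (0.0723) or TAZ uKO section 2 (0.19). In none of these lists did a member pass over the list alone.

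**Figure D3:**
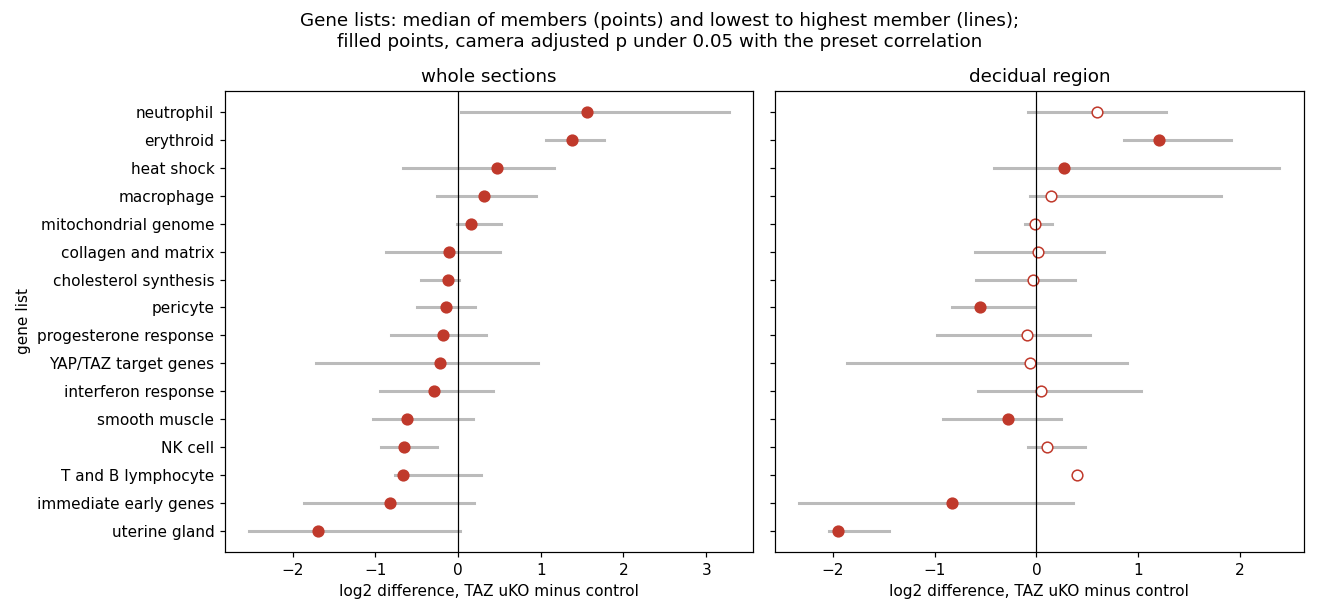
Median log2 difference (points) and range of members (lines) of the 16 lists called in whole sections, there and in the decidual region (TAZ uKO minus control), with filled points for lists that camera called with the preset correlation. The erythroid list had medians of 1.38 and 1.20.

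The second comparison was made within the decidual region. The mix of its 2 clusters differed between the groups: the Crabp1 and Igfbp3 cluster held 40 of 193 and 14 of 66 decidual spots in control sections 1 and 2, and 45 of 164 and 49 of 129 in TAZ uKO sections 1 and 2. Spon2 again had the smallest p, at 53.2 ± 0.373 CPM in control and 317.9 ± 92.6 CPM in TAZ uKO sections (log2 difference 2.58 ± 0.24, adjusted p = 0.177). Metallothioneins, which bind zinc and other metals, were lower: Mt2 was at 1235 ± 258 against 324 ± 56.1 CPM (-1.93 ± 0.22) and Mt4 at 32.9 ± 1.76 against 7.48 ± 0.71 CPM (-2.13 ± 0.23), each with an adjusted p of 0.218. Ak1, an adenylate kinase, was at 51.3 ± 7.18 against 121.2 ± 14.5 CPM. Crabp1 (1.44 ± 0.24) and Lrat, which esterifies retinol (-1.30 ± 0.17), also stood out, but both are genes that define the clusters of this region. The named genes did not pass correction, and edgeR called 0 of 11245 genes, with 569 at an unadjusted p under 0.05, where DESeq2 called 27 (12 higher and 15 lower) and limma voom 0. Without TAZ uKO section 1 edgeR called 950 genes and without TAZ uKO section 2 it called 929.

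In the decidual region camera called 12 lists, 4 higher and 8 lower, and 0 with an estimated correlation (lowest adjusted p = 0.572). Immediate early genes were lower (10 of 11, 6 over the list alone, median -0.83, adjusted p = 2.79e-12, and 0.572 as an adjusted p with an estimated correlation). Egr1 was at 59.1 ± 16.5 against 11.6 ± 8.27 CPM and Fos at 92.8 ± 17.2 against 31.3 ± 15.8 CPM. Uterine gland genes were lower here too (3 of 3, all over the list alone, median -1.94, adjusted p = 3.41e-09, and 0.579 as an adjusted p with an estimated correlation), and erythroid genes higher (4 of 4, 2 over the list alone, median 1.20, adjusted p = 6.6e-10, and 0.572 as an adjusted p with an estimated correlation). DNA replication genes were lower (19 of 20, none over the list alone, adjusted p = 5.42e-05). The replication clamp Pcna was at 240.1 ± 9.11 against 166.9 ± 4.4 CPM and the helicase subunit Mcm3 at 77.2 ± 6.52 against 57.4 ± 4.01 CPM. Pericyte genes (9 of 9, adjusted p = 5.72e-05) and smooth muscle genes (11 of 12, adjusted p = 0.000426) were lower, with no member over the list alone. For these 3 lists the adjusted p was 0.684 with an estimated correlation. Endothelium genes were lower (10 of 17, adjusted p = 0.0174, and 0.777 as an adjusted p with an estimated correlation). The member lower over the list alone was the endothelial cadherin Cdh5, at 178 ± 11 against 92.1 ± 5.6 CPM. Lymphatic endothelium genes were lower (3 of 3, 2 over the list alone, adjusted p = 9.75e-05, and 0.572 as an adjusted p with an estimated correlation). Heat shock genes (8 of 10, 2 over the list alone, adjusted p = 0.00185), matrix proteases and their inhibitors (13 of 14, adjusted p = 0.00713) and WNT signalling genes (14 of 19, adjusted p = 0.0282) were higher, and the 2 inflammatory mediators measured were lower (adjusted p = 0.0282), all with an adjusted p of 0.684 with an estimated correlation. Of these lists, the call was lost or turned without TAZ uKO section 2 for heat shock (0.578), endothelium (0.652), inflammatory mediators (0.303), smooth muscle (0.226) and pericytes (0.0678). Without TAZ uKO section 1 it was lost or turned for matrix proteases and lost for WNT signalling. Without control section 1 it was lost for WNT signalling (0.152), matrix proteases (0.0947) and inflammatory mediators (0.0715), and without control section 2 for endothelium (0.136), inflammatory mediators (0.114) and smooth muscle (0.0528). Decidualization genes (11 of 25 higher, adjusted p = 0.614), YAP and TAZ targets (9 of 20 higher, adjusted p = 0.485) and progesterone response genes (adjusted p = 0.287) were not called in this region. The region leaves out cluster 7, which scored higher for decidualization genes but also for trophoblast (1.338) and epithelium (2.397).

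In the third comparison, within the muscle region, single genes passed correction. The Nppa cluster held 82 of 295 and 25 of 92 muscle spots in control sections 1 and 2, and 31 of 121 and 23 of 136 in TAZ uKO sections 1 and 2. All 4 adult hemoglobin genes rose: Hbb-bs, on chromosome 7 from 103826523 to 103827928, by 2.84 ± 0.17 on the log2 scale (80.2 ± 3.25 against 574.1 ± 66.7 CPM, adjusted p = 0.000847), Hbb-bt by 3.26 ± 0.22, Hba-a1 by 2.94 ± 0.22 and Hba-a2 by 3.02 ± 0.24. The complement gene C4b rose by 2.01 ± 0.24 (28.1 ± 1.45 against 113.9 ± 34.7 CPM) and Wfdc17, a secreted protein of macrophages, by 2.75 ± 0.35. Among genes that fell were the fibril-associated collagen Col12a1 (277.8 ± 16.2 against 106.9 ± 5 CPM, log2 difference -1.38 ± 0.16), the microfibril protein Ltbp2 (-1.81 ± 0.23), the angiogenic factor Pgf (-1.61 ± 0.22) and Angptl7 (-2.02 ± 0.25), which also leads a cluster of this region. Adjusted p lay between 0.000847 and 0.0462. In all, edgeR called 14 of 11001 genes, 10 higher and 4 lower. The other 4, named after their values were seen, were the lipid carrier Apoe (243.3 ± 35.2 against 732.3 ± 54.7 CPM), the interleukin-4 receptor Il4ra, the macrophage lectin Mgl2 and the retinaldehyde dehydrogenase Aldh1a3, all higher in TAZ uKO sections. Without TAZ uKO section 1 the count was 614 and without TAZ uKO section 2 it was 701. Col12a1 was no longer called without control section 1 (adjusted p = 0.126) or control section 2 (0.124), nor were Ltbp2 (0.131) and C4b (0.0675) without control section 1, nor Pgf without control section 1 (0.0555) or 2 (0.104). The calls also depended on which spots counted as muscle: coarser clustering or scaling over all sections together left 0 genes, and finer clustering left 1, Hbb-bs. With coarser clustering and scaling together no vascular region formed, and muscle held more spots (487 and 510 against 295 in control section 1). On the main muscle spots limma voom called 7 higher and 1 lower gene. The replicate block called 4 higher and 0 lower, so none of the falls was called there.

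Of the lists, 17 were called in the muscle region, a test added after the data were seen, 8 higher and 9 lower. Erythroid genes rose together (4 of 4, each over all genes and over the list alone, median 2.98, adjusted p = 7.94e-89, and 0.0818 as an adjusted p with an estimated correlation, the lowest of any list). Macrophage genes were higher (14 of 14, 9 over the list alone, median 1.05, adjusted p = 2.81e-19). Among them were the receptor Csf1r at 32.2 ± 1.82 against 70.8 ± 10.8 CPM and the lysozyme Lyz2 at 164.4 ± 56.7 against 439.7 ± 137 CPM. Adipocyte genes were higher too without being called (4 of 4, none over the list alone, median 1.56, adjusted p = 0.33). Finer clustering gave a cluster led by the fat genes Cfd, Fabp4 and Car3 with Wfdc17, which held 32 of its 41 spots in TAZ uKO section 2. With scaling together a similar cluster, with 66 of 73 spots in that section, counted as muscle. Both measured neutrophil genes were higher (2 over the list alone, adjusted p = 1.96e-05), and NK cell genes lower (4 of 4, 2 over the list alone, adjusted p = 0.000214). YAP and TAZ targets were lower (17 of 22, 3 over the list alone, median -0.23, adjusted p = 5.12e-05). Among them were Ccn1 at 138.4 ± 53 against 37.6 ± 9.64 CPM, the ecto-nucleotidase Nt5e at 37.6 ± 14.2 against 12.1 ± 1.81 CPM and Ankrd1, a cardiac and muscle ankyrin protein, at 10.3 ± 2.75 against 2.56 ± 1.25 CPM. Immediate early genes were lower (11 of 12, 5 over the list alone, adjusted p = 1.74e-08), as were uterine gland genes (3 of 3, 1 over the list alone, adjusted p = 0.000652). The macrophage, neutrophil, NK cell, YAP and TAZ, immediate early and gland lists had an adjusted p of 0.528 with an estimated correlation. Smooth muscle genes were lower even within this region (11 of 12, 4 over the list alone, median -0.31, adjusted p = 3.62e-05, and 0.559 as an adjusted p with an estimated correlation). Acta2, smooth muscle actin, was at 9858 ± 716 against 7062 ± 357 CPM. Cholesterol synthesis genes were lower (14 of 15, none over the list alone, median -0.58, adjusted p = 1.45e-05, and 0.592 as an adjusted p with an estimated correlation). Idi1, of this pathway, was at 32.9 ± 7.38 against 15.3 ± 4.21 CPM. The call was lost without control section 1 (adjusted p = 0.0927). The neutrophil call was lost without TAZ uKO section 1 (0.688), and so was the NK cell call (0.229).

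Other lists called in muscle had calls that 1 section could end. Collagen genes were lower (21 of 30, 1 lower over all genes, 1 higher and 2 lower over the list alone, adjusted p = 0.0074, and 0.7 as an adjusted p with an estimated correlation), lost without control section 2 (0.261). Progesterone response genes were lower (10 of 11, none over the list alone, adjusted p = 0.00233, lost without TAZ uKO section 2 at 0.0984), and estrogen response genes higher (6 of 9, 3 over the list alone, adjusted p = 0.00462, lost without TAZ uKO section 2 at 0.35), among them complement C3 at 249.5 ± 27.2 against 688.7 ± 491 CPM. Inflammatory mediators were higher (7 of 8, none over the list alone, adjusted p = 0.00846, lost without control section 1 at 0.0564 or TAZ uKO section 2 at 0.739). These 3 lists had an adjusted p of 0.528 with an estimated correlation. Lymphatic endothelium genes (4 of 4, none over the list alone, adjusted p = 0.00676, lost without TAZ uKO section 2 at 0.502) and matrix proteases (12 of 16, 2 higher and 1 lower over the list alone, adjusted p = 0.0405, lost without control section 1 at 0.375 or TAZ uKO section 1 at 0.126) were higher, both with an adjusted p of 0.559 with an estimated correlation. Mitosis genes were lower (19 of 20, none over the list alone, adjusted p = 0.0258, and 0.851 as an adjusted p with an estimated correlation) and turned without control section 1 (0.314) or TAZ uKO section 1 (0.715). The epiblast and visceral endoderm list had 1 measured gene, the retinol carrier Rbp4, higher with an adjusted p of 0.0351 (0.528 as an adjusted p with an estimated correlation; 0.12 without control section 1 and 0.504 without TAZ uKO section 2). Decidualization genes (13 of 24 higher, adjusted p = 0.829) and epithelium genes (adjusted p = 0.941) were not called.

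The fourth comparison was within the outer stroma region. The mix of its 3 clusters differed between the groups: the Sfrp4 cluster, also led by the antibody genes Igkc and Igha, held 222 of 530 and 50 of 157 of its spots in control sections 1 and 2, and 127 of 427 and 71 of 341 in TAZ uKO sections 1 and 2. Spon2 was at 114 ± 20.3 CPM in control and 545.2 ± 19.7 CPM in TAZ uKO sections (2.26 ± 0.19, adjusted p = 0.186), Crabp1 at 21.9 ± 0.622 against 78.2 ± 10.3 CPM (1.84 ± 0.17, adjusted p = 0.187) and Inhbb at 19 ± 1.81 against 76.4 ± 24.2 CPM (2.02 ± 0.26, adjusted p = 0.33). Aff3, a nuclear protein of transcription elongation complexes (-1.92 ± 0.21, adjusted p = 0.281), Fmod (-1.88 ± 0.21, adjusted p = 0.309) and the ion transport regulator Fxyd3, a gene of the gland cluster (-2.20 ± 0.26, adjusted p = 0.31), were lower in both TAZ uKO sections. These 6 genes did not pass correction, and edgeR called 0 of 13311 genes, with 674 at an unadjusted p under 0.05. DESeq2 called 45 (16 higher and 29 lower) and limma voom 0. The edgeR test called 1731 genes without TAZ uKO section 1, 1288 without TAZ uKO section 2 and 2 without control section 2.

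A list test added after the data were seen called 15 lists in this region, 5 higher and 10 lower. All 21 measured interferon response genes were lower, 8 over the list alone (median -0.78, adjusted p = 1.87e-16, and 0.511 as an adjusted p with an estimated correlation). The antiviral gene Rsad2 was at 8.72 ± 1.86 against 2.81 ± 0.056 CPM, Ifit3 at 7.59 ± 4.45 against 2.2 ± 0.211 CPM and the chemokine Cxcl10 at 3.67 ± 0.826 against 1.04 ± 0.458 CPM. Immediate early genes (10 of 12, 8 over the list alone, adjusted p = 1.85e-10), smooth muscle genes (11 of 12, 3 over the list alone, adjusted p = 1.48e-07), uterine gland genes (3 of 3, 2 over the list alone, median -2.61, adjusted p = 2.04e-07) and progesterone response genes (12 of 16, 1 over the list alone, adjusted p = 0.00524) were lower. Erythroid genes (4 of 4, 3 over the list alone, median 1.12, adjusted p = 1.57e-12), heat shock genes (9 of 10, 2 over the list alone, adjusted p = 2.98e-06), neutrophil genes (2 of 2, both over the list alone, adjusted p = 3.57e-06) and WNT signalling genes (14 of 20, none over the list alone, adjusted p = 0.00185) were higher. Among the last, Lef1, a transcription factor of the pathway, was at 20.4 ± 0.715 against 34.3 ± 0.877 CPM and the ligand Wnt4 at 78.7 ± 9.66 against 140.4 ± 49.6 CPM. Collagen genes (21 of 30, none over the list alone, adjusted p = 0.00555) and YAP and TAZ targets (16 of 21, 1 higher and 1 lower over the list alone, adjusted p = 0.0224) were lower, with Amotl2 at 114.2 ± 6.98 against 62.4 ± 7.17 CPM. The lists since the interferon genes all had an adjusted p of 0.511 with an estimated correlation. NK cell genes were lower (10 of 11, adjusted p = 0.00106) and mitochondrial genes higher (12 of 12, adjusted p = 0.00266), both with an adjusted p of 0.616 with an estimated correlation, and pericyte (8 of 9) and T and B lymphocyte genes (3 of 3) were lower (adjusted p = 0.0374 each, and 0.545 as an adjusted p with an estimated correlation). In these 4 lists no member passed over the list alone. Calls were lost without control section 1 for progesterone response (0.125), mitochondrial (0.424), pericyte (0.223) and lymphocyte genes (0.424). They were lost without control section 2 for YAP and TAZ targets (0.0614) and pericytes (0.0623). Without TAZ uKO section 1 they were lost for WNT signalling (0.899), NK cell (0.909), lymphocyte (0.572) and mitochondrial genes (0.127). Without TAZ uKO section 2 they were lost for heat shock (0.537), YAP and TAZ targets (0.433), pericyte (0.332) and collagen genes (0.141). Decidualization genes were not called (13 of 25 higher, 2 over the list alone, adjusted p = 0.0905).

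Further regions were compared after the data were seen. In the granzyme-led region Spon2 rose from 134.6 ± 28.6 to 411.8 ± 6.2 CPM (log2 difference 1.60 ± 0.18, adjusted p = 0.0314), the only gene of 10878 that edgeR called there. The inducible heat shock genes Hspa1a (2.38 ± 0.35) and Hspa1b (2.18 ± 0.32) were higher without passing (adjusted p = 0.0939 each), and Hsd11b2, which inactivates glucocorticoids, was at 64.5 ± 7.29 against 20.9 ± 1.94 CPM (adjusted p = 0.0663). The Spon2 call was lost with a minimum of 10 CPM (adjusted p = 0.0506) and with scaling over all sections together (0.421). The count was 28, 25, 179 and 531 without control section 1, control section 2, TAZ uKO section 1 and TAZ uKO section 2. In the vascular region Ren1, the renin gene, on chromosome 1 from 133350674 to 133360320, rose from 7.54 ± 4.58 to 57 ± 1.8 CPM (2.62 ± 0.33, adjusted p = 0.0456), the only gene of 10058 called. The chemokine Ccl8 (1.46 ± 0.23) was higher, and Col11a1 (-1.59 ± 0.25) and the epithelial gene Prap1 (-1.72 ± 0.26) were lower without passing (adjusted p = 0.128 each). Ren1 was not called with a minimum of 10 CPM (adjusted p = 0.0532) or by limma voom (0.0691). Leaving out the same sections in turn gave 16, 26, 291 and 440 genes. In cluster 7 edgeR called 0 of 8976 genes, with 290 at an unadjusted p under 0.05, DESeq2 called 1 and limma voom 0. Leaving out TAZ uKO section 1 or 2 gave 94 and 75 genes there. Spon2 (2.03 ± 0.32) and the opioid-related precursor Pnoc (1.44 ± 0.28) were higher in cluster 7, and the nucleotidase Nt5c3 (-1.75 ± 0.26) and the ion transporter Slc4a11 (-1.84 ± 0.37) were lower, each with an adjusted p of 0.999. The planned fit of the gland region could not be made, since fewer than 20 gland spots were found in 3 of the 4 sections.

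The last comparison asked whether the genotype effect differs between the decidual region (without cluster 7) and the muscle region, testing the difference within sections. It did so for 16 of 12086 genes, 3 with a higher and 13 with a lower effect in the decidual region, and 944 genes had an unadjusted p under 0.05. The metallothioneins Mt1 and Mt2 had the smallest adjusted p, with Mt1 at -1.62 in the decidual region and 0.35 in muscle (difference -1.95 ± 0.17, adjusted p = 0.000214) and Mt2 at -1.93 and -0.37 (difference -1.56 ± 0.17, adjusted p = 0.0014). Spon2 was higher by 2.58 in the decidual region and 1.07 in muscle (difference 1.49 ± 0.17, adjusted p = 0.00228). Its mean level was 53.2 CPM in control and 317.9 CPM in TAZ uKO decidual regions, and 224.3 and 469.9 CPM in muscle. The smaller log2 effect in muscle thus came with a higher control level, and a difference on the CPM scale was not tested. Apoe differed by 0.21 in the decidual region and 1.59 in muscle (difference -1.38 ± 0.18, adjusted p = 0.00684), and Hba-a1 by 0.86 and 2.94 (difference -2.06 ± 0.30, adjusted p = 0.0138). Coarser clustering ended the calls of Spon2 (adjusted p = 0.0762), Apoe (0.0762) and Hba-a1 (0.266), and finer clustering that of Hba-a1 (0.63). The number of genes was 38, 31, 118 and 70 without control section 1, control section 2, TAZ uKO section 1 and TAZ uKO section 2.

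**Figure D4:**
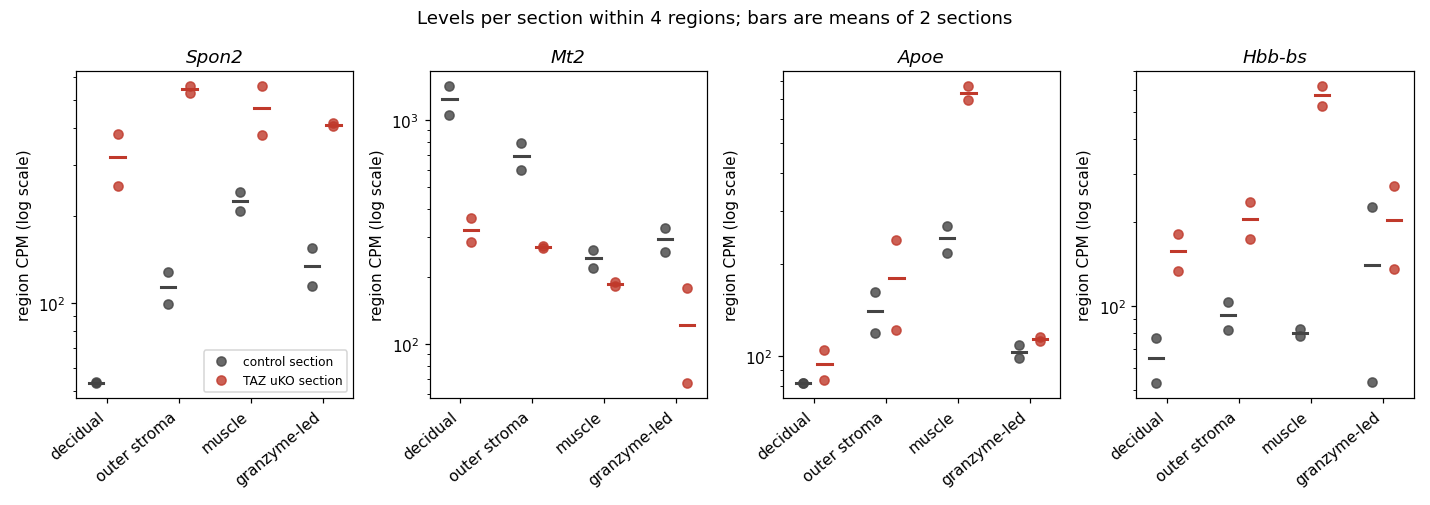
Level of Spon2, Mt2, Apoe and Hbb-bs in 4 regions of each section, in CPM on a log axis, with points for sections and bars for group means. Mt2 in the decidual region was at 1235 CPM in control and 324 CPM in TAZ uKO sections on average, and Hbb-bs in the muscle region at 80.2 and 574.1 CPM.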

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

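The difference between regions in the genotype effect was tested by a fit fixed before the data were examined, while the piece values and the blood test were chosen after the result was seen. The effect of genotype differed between the decidual and the muscle region for 16 genes. The log2 effect in the decidual region minus that in muscle was -1.953 for Mt1, -1.555 for Mt2, 1.486 for Spon2, -1.38 for Apoe and -2.061 for Hba-a1. Pieces were counted for Mt2 in the decidual region only, where it was at 247 to 384 CPM in the 4 TAZ uKO pieces and 1008 to 1390 in the 4 control pieces. Spon2 over all spots of a piece was at 399 to 502 against 130 to 134. Piece values here and gland region values below are scaled to their own UMI total, without TMM normalization. Pieces of 1 section are not replicates, and their animals are not given.

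Hemoglobin genes were higher in the muscle region of the TAZ uKO sections. The log2 differences of the 4 adult genes had a range of 0.417, but this test was written after they were seen, near-identical genes may share reads, and in the decidual region the same genes differed by 0.86 (Hba-a1) to 1.91 (Hba-a2), so it does not show blood as the cause. Hbb-bs in single muscle pieces ranged from 208 to 783 in TAZ uKO and from 58.2 to 92.8 in control sections. Which spots count as muscle also matters: with other clusterings the log2 difference of Hbb-bs was as low as 1.555, and the table of tests cannot tell this cause from a difference within muscle. Whether blood in the tissue accounts for the difference stays open.

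Gland genes were lower in regions outside the gland. Transcripts spreading from gland spots could do this. The ratio of Spink1 to Prss29 in 3 other regions lay near that of the gland region of the same section in most cases (median absolute log2 difference 0.209). It departed by 1.057 in the decidual region of TAZ uKO section 2, and by -0.621 and -0.597 in the granzyme-led region of control section 2 and TAZ uKO section 1. Gland cells lying under spots of those regions would give a near ratio as well, so the ratio cannot tell spread from such spots. Fewer gland spots could do it too: inside the gland region Prss28, Prss29 and Spink1 differed by -0.387 on average, but TAZ uKO section 2 was below both control sections for all 3, and section 1 was within their range for Spink1 and Prss28 and above it for Prss29, with Spink1 at 32438 and 23340 CPM in control and 26517 and 5414 CPM in TAZ uKO sections, Prss28 at 18030 and 13648 against 17330 and 6461 CPM, and Prss29 at 23486 and 15350 against 33120 and 7235 CPM. With 8 gland spots in TAZ uKO section 2, whether glands were fewer, weaker or missed by the section stays open.

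Targets of YAP and TAZ were lower as a list in whole sections. Without muscle and vascular spots the median log2 difference moved from -0.218 to -0.102 (camera unadjusted p = 0.00371), so the smaller muscle share may carry a part, and this cannot be told apart from a fall within cells. Without the members Ccn1 and Ccn2, which growth factors also induce, the median was -0.148 and camera gave an unadjusted p of 0.016. With an estimated correlation that p was 0.193, so whether these members carry the shift stays open. The list was not called in the decidual region but was lower within muscle (17 of 22, adjusted p = 5.12e-05) and outer stroma (16 of 21, adjusted p = 0.0224), with an adjusted p of 0.528 and 0.511 with an estimated correlation. Smooth muscle genes were also lower within both of these regions (11 of 12 in each, medians -0.31 and -0.51). The region fits therefore do not set muscle content aside. In the decidual region smooth muscle genes were lower as well (11 of 12, median -0.28). There 9 of 20 YAP and TAZ targets were higher and camera did not call the list (adjusted p = 0.485). A lower smooth muscle list thus did not always come with a call of the targets. Whether TAZ loss itself lowers these genes stays open.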

How the results depend on the processing

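The alternatives were fixed before the data were examined, except for 3 subsets of whole-section spots, the granzyme-led, cluster 7 and vascular fits, the list tests in muscle and outer stroma, and clustering without leading genes, which were added after the data were seen. Values are numbers of called genes, lists or separate regions unless stated. The whole-section fit called 0 genes, DESeq2 89, no low-count filter 55 and the 3 added subsets 0. In the decidual region (0 genes) DESeq2 called 27. In muscle (14) DESeq2 called 38, no filter 253, limma voom 8 and the fit without mitochondrial, hemoglobin and ribosomal protein genes 7. Muscle spots from Leiden 0.3, from Leiden 1.0 and from scaling together gave 0, 1 and 0. In outer stroma (0) DESeq2 called 45, no filter 232 and Leiden 0.3 1. In the granzyme-led region (1) DESeq2 called 5, no filter 75, a minimum of 10 CPM 0, Leiden 1.0 2 and scaling together 0. In cluster 7 (0) DESeq2 called 1 and no filter 89. In the vascular region (1) DESeq2 called 2, no filter 78, a minimum of 10 CPM 0, limma voom 0 and Leiden 1.0 6. At Leiden 1.0 that region also held a cluster led by Cfd and Fabp4, with 32 of 41 spots in TAZ uKO section 2. The interaction (16) fell to 10 with a minimum of 10 CPM and 2 at Leiden 0.3, and rose to 54 at Leiden 1.0. Why the counts move was not tested.

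The labels give the sections of each group replicate numbers, which need not pair them. With a replicate block the whole-section, decidual, muscle, outer stroma, granzyme-led and vascular fits called 0, 1, 4, 15, 55 and 2 genes. Deviations of equally numbered sections from their group means correlated at -0.086 in whole sections.

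Leaving out 1 section gave 0 to 522 genes in whole sections, 0 to 950 in the decidual region, 12 to 701 in muscle, 0 to 1731 in outer stroma, 25 to 531 in the granzyme-led region, 0 to 94 in cluster 7, 16 to 440 in the vascular region and 31 to 118 for the interaction. The high counts come from leaving out a TAZ uKO section: the spread then rests on the control pair (SD of log2 level 0.153 against 0.328), and the lone TAZ uKO section is assumed to vary as little. Among genes the result Cfd, muscle region genotype effect was the only one to turn direction with a call, from -6.09 without TAZ uKO section 2 to 8.94 without control section 2. The log2 difference of Wwtr1 ranged from 0.09 to 0.393 without a call.

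With an estimated correlation camera called 0 lists in whole sections, 0 in the decidual region, 0 in muscle and 0 in outer stroma, and fry called 0, 0, 2 and 0, where the 2 were erythroid and Hippo core genes (adjusted p = 0.0384). The preset correlation leaves out that genes of some lists move together between sections. In whole sections the estimate was 0.00373 for YAP and TAZ targets and -0.0423 for progesterone response genes, both under the preset 0.01. Genes moving together therefore cannot account for the loss of these calls. Leaving out 1 section, called lists that turned direction had adjusted p from 1.24e-06 to 0.409 (cholesterol synthesis) and 1.18e-18 to 0.371 (heat shock) in whole sections. In the decidual region these were 2.83e-09 to 0.739 (matrix proteases), 6.31e-09 to 0.578 (heat shock) and 5.85e-06 to 0.652 (endothelium), and in muscle 5.39e-10 to 0.715 (mitosis). Erythroid, immediate early and uterine gland lists were called in all 4 fits with any section left out. In outer stroma the interferon list was too.

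Region shares separated in 5 regions, in 3 at Leiden 0.3 and in 3 without the leading genes at an unadjusted p under 0.05. At Leiden 0.3 the gland region did not separate, but its cluster there was also led by Sfrp4, Igkc and Igha. Of the 10 named muscle genes that passed, DESeq2 called 10, limma voom 6, Leiden 0.3 0, Leiden 1.0 1 and scaling together 0. Over all named values 8878 were recomputed, 146 changed sign, and 1 of these with a call. The vascular fit was not run at Leiden 0.3 or with scaling together, where no such region formed. The epithelial fit was not run, with under 20 gland spots in 3 sections. Its alternatives were not run either, also not at Leiden 0.3, where the gland region held 67 to 295 spots per section. The smallest fitted sum, the vascular region of control section 2, held 697307 UMIs.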

Other observations

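The observations below were gathered after the main results were seen. Several lists leaned to 1 side without a call. In the decidual region 14 of 19 hypoxia and glycolysis genes were higher (adjusted p by camera 0.122, and 0.728 with an estimated correlation). In the whole sections 19 of 20 mitosis genes and 17 of 20 DNA replication genes were lower (adjusted p by camera 0.126 and 0.226). The WNT list, called higher in outer stroma and the decidual region only with the preset correlation (adjusted p = 0.511 and 0.684 with an estimated correlation), had members on both sides in the decidual region, such as Wnt11 (log2 difference 1.36), a ligand, and Notum (-0.55), an inhibitor of WNT ligands. No member of it passed over the list alone. Trophoblast genes (7 of 9 higher, adjusted p by camera 0.515) and adipocyte genes (4 of 5 higher, 0.37) were not called in the whole sections. Cfd, an adipocyte protease, changed sign with the section left out.

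In single pieces Crabp1 was at 115 to 181 CPM in TAZ uKO and 35.4 to 54.2 in control sections. Spon2 was higher in every region tested, by 0.84 in the vascular region to 2.58 in the decidual region. A gene that differs in all regions could reflect a change in many cell types or transcripts spread over the section, and no test here separates these: the smallest region effect came with an adjusted p of 0.475 by edgeR, and without TAZ uKO section 1 the whole-section fit called 349 genes.

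The TAZ uKO sections varied more between replicates than the control sections, with 306 against 35 genes apart by more than 2-fold. The number of pieces runs the other way, with 3 and 1 in the control sections and 2 in each TAZ uKO section. The cause was not tested.

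Measurements that would settle open points are hemoglobin-free counts of vessels and macrophages in the muscle layer, a count of glands per site, and reads over the floxed part of Wwtr1. The lowest log2 difference of Hbb-bs over other clusterings, 1.555, could be sharpened by naming muscle from images.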
